A study of Rattus norvegicus with 10 samples.

How the data were processed

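RNA was measured in exosomes, the small vesicles that cells release into body fluids, from the plasma of 10 male Wistar rats. Per the labels, 5 rats had undergone remote ischemic conditioning (RIC), a treatment in which blood flow to a distant part of the body is briefly stopped and restored, and 5 were healthy controls. RIC consisted of 4 cycles, each of 5 min of ischemia and 5 min of reperfusion. Titles, sources and the condition label separate the groups, while the treatment text is identical for all 10 animals and was taken to apply to the RIC rats only. The body part, and the time from the last cycle to blood sampling, are not given in the sources used here. Per the labels' protocols, 10 mL of venous blood was drawn into EDTA tubes from each animal, exosomes were separated by differential ultracentrifugation, total RNA was extracted with TRIzol and an RNeasy column, and biotin-labelled cRNA was hybridised to an Affymetrix array.

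The authors deposited 1 table of log2 values, with 1 column per animal and 1 row per transcript cluster, which is the array's unit of measurement and groups the probes of a transcribed region. The values were made with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summarisation algorithm and the normalization are not given in the sources used here, nor is the genome build of the clusters, so no coordinates are printed. The deposited log2 values had 2 decimals, a lowest value of 2.71 and a highest of 19.93, and array medians between 4.05 and 4.23. A total of 1211 clusters sat at 19.93 on all arrays, and 226 others had a single lower value on all arrays. Such clusters cannot show a difference between groups. Values that stop at such a ceiling compress differences of the most abundant RNAs, and signal near the floor compresses those of the dimmest. What set the ceiling is not given in the sources used here.

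The series is labelled as exosomal microRNA, but the table held 68842 rat transcript clusters of a whole-transcriptome array, with no probe sets for mature miRNA arms. The test for changed mature miRNAs, planned before the data were examined, was therefore run on all transcript clusters. The plan named that set for a table without probe names, and it was used here because mature probe sets were absent. The test planned for miRNA hairpins was run on the 398 clusters annotated to a miRNA gene (381 symbols). The planned miRNA lists, haemolysis index and median of detected miRNAs also used those clusters. A miRNA gene cluster measures RNA from the gene's locus, primary transcript included, and not the mature arm. Fixed lists of mature miRNAs were mapped to their genes. Averages over probe sets of orthologues could not be formed. Symbols came from the platform annotation given for this work. Of the clusters, 23456 had 1 symbol, 495 had several and 44891 had none there. Symbols of 22077 clusters were matched to a RefSeq gene table by gene number, which updated 1 symbol. Where a gene had several clusters, the cluster with the highest mean over all arrays stood for it in the lists. Among 1167 genes with several varying clusters, 378 had clusters that differed in sign.

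Groups were compared as RIC minus control, 5 against 5, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values, without further normalization, filter or covariate. P-values were adjusted by the Benjamini-Hochberg method, over all clusters or over the miRNA gene clusters alone, with a threshold of 0.05. The animals were separate, so p-values measure the spread between these 10 rats. Single values per sample were compared with two-sided exact permutation tests over all 252 assignments of 5 against 5, for which the smallest p is 0.00794. The limma step was tested on simulated data with 200 changed clusters among 68842. It recovered 31.5% of them at a log2 change of 1, 68.5% at 2 and 86.5% at 3, with 2, 5 and 14 false calls. The changed clusters were drawn from those with a mean of 6 to 18, with noise independent between clusters. The recovery therefore does not describe dimmer clusters, most miRNA genes among them.

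Before the data were examined, 13 miRNA lists were fixed: erythrocyte and haemolysis, platelet, leukocyte, muscle, endothelial and angiogenic, hypoxia, conditioning miRNAs from the literature, liver, brain, the let-7 family, the miR-17-92 cluster and its paralogues, the miR-29 and miR-30 families, and the Dlk1-Dio3 cluster. Another 18 gene lists were written after the array was found to cover all genes and after levels had been seen, but before the groups were compared over them. They covered platelet, erythroid, neutrophil, monocyte, lymphocyte, endothelial, skeletal muscle, heart, liver, brain, exosome biogenesis, hypoxia target, immediate early and heat shock, inflammatory, interferon, ribosomal protein, oxidative phosphorylation, and olfactory and vomeronasal receptor genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over its lists.

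The level taken as background was the median of all cluster means, 4.14. A stricter level was added after the data were seen, the 95th percentile of 1446 clusters of olfactory and vomeronasal receptor genes, 4.38, because these receptors belong to sensory neurons. The genes named were chosen by a rule set before the data were examined. When fewer than 6 were called, it took the 6 largest differences in each direction among those above background with an unadjusted p under 0.05. It was applied to all named clusters and to miRNA genes. It also took a fixed set of miRNAs, the 2 members of each list with the smallest p, and at most 2 unnamed clusters per direction. The fixed set included miR-21, which is not analysed here. Alternatives covered normalization between arrays, filters on dim clusters, variance models, a replicate block, other thresholds, other list tests, and leaving out each sample.

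Scan dates and array batches are not used here. The number of arrays and the signal over background limit the precision, since array values carry no read depth.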

Results

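Plasma exosome RNA of 5 control rats and 5 rats that had undergone remote ischemic conditioning (RIC) was profiled on whole-transcriptome arrays, and values are given as log2 signal, mean ± SD. Of 68842 transcript clusters, 7603 (11%) had a mean above 6. Clusters of olfactory and vomeronasal receptor genes, which served as a measure of background, had a median of 4.01 and a 95th percentile of 4.38. Arrays correlated with one another at 0.976 or more. The first principal component held 24.5% of the variance and placed all 5 RIC samples above all 5 controls (exact permutation p = 0.00794, the smallest these groups can give). It was computed on the deposited values alone and not repeated on rescaled ones. Control sample 2 lay at -65.3 on that component, and control sample 1 at 52.2 on the next, which held 15.9%, farther out than the other controls.

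Some genes of platelets and red cells had values at the ceiling in both groups. Of 33 platelet genes measured, all 33 lay above the receptor 95th percentile, with a median level of 17.87. Among them, 10 had the same value on all arrays, which for Pf4, the chemokine of platelet alpha granules, and Tubb1, the platelet beta-tubulin, was the ceiling of 19.93. The globin genes Hba-a1 and Hbb-bs sat at 19.93 on all arrays as well, and 28 of 29 erythroid genes exceeded the receptor 95th percentile, with a median level of 6.32. Cd9, a tetraspanin of exosome membranes, and Sdcbp, which encodes the vesicle-forming adaptor syntenin, were likewise at 19.93, as were 1211 clusters in all. These genes were picked after their values were seen. Probes of different genes bind with different strength, so levels do not rank RNA classes by amount. Ribosomal protein genes had a median level of 7.86, with 282 of 318 above the receptor 95th percentile, and 9 of 20 neutrophil, 2 of 19 liver and 2 of 17 brain genes exceeded it. The miRNA gene clusters had a median of 4.01, close to that of the receptors. Of the 398, 103 (25.9%) exceeded 4.38 and 11 exceeded 6.

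The main comparison asked which exosomal RNAs differed after RIC. Gpr15lg, which encodes a ligand of the receptor GPR15, had the largest positive difference among named genes above background with an unadjusted p under 0.05, with 13.06 ± 1.27 in RIC and 9.78 ± 1.70 in control (n = 5 each, log2 difference 3.28, SE 0.89). Carbonic anhydrase Car1 followed with 8.07 ± 1.03 against 6.52 ± 0.36, and the histone gene Hist2h3c2 with 12.16 ± 0.87 against 10.66 ± 0.32. Ndufa1, a subunit of respiratory complex I, differed by 1.27, the red-cell anion exchanger Slc4a1 by 1.09 and Rps25l3 by 1.09. In the other direction, Rab5a, a GTPase of early endosomes, measured 12.84 ± 0.95 in control with a log2 difference of -1.84 (SE 0.46) in RIC. Chrdl1, an antagonist of bone morphogenetic proteins, measured 9.90 ± 0.79 in RIC and 11.74 ± 0.33 in control. Zwint, a kinetochore component, differed by -1.70, the small nucleolar RNA Snord22 by -1.64, the potassium channel Kcna3 by -1.61 and sorcin (Sri) by -1.59.

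None of these genes passed the test. With limma, 0 of 68842 clusters had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.302. At an unadjusted p under 0.05 there were 7665 clusters (11.1%), of which 5485 had a positive and 2180 a negative difference. That split followed the scaling, with 71.6% positive in the deposited values, 26.8% after centring each array on its median and 48.4% after removing each array's level-dependent trend. A trended, robust variance model also gave 0 clusters, with 7324 at an unadjusted p under 0.05, and array weights gave 0, with 7297. Among clusters with no symbol in the annotation, TC1600000903.rn.1 (1.84) and TC1500001902.rn.1 (1.69) had the largest positive differences by the same rule, and TC0900002592.rn.1 (-3.26) and TC1000002741.rn.1 (-3.10) the largest negative ones. TC1600000903.rn.1 had a control mean of 4.13, under the median of all clusters. For TC1000002741.rn.1, 1 control sample sat at the ceiling, so its difference is a low estimate. None of the 4 passed.

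**Figure D1:**
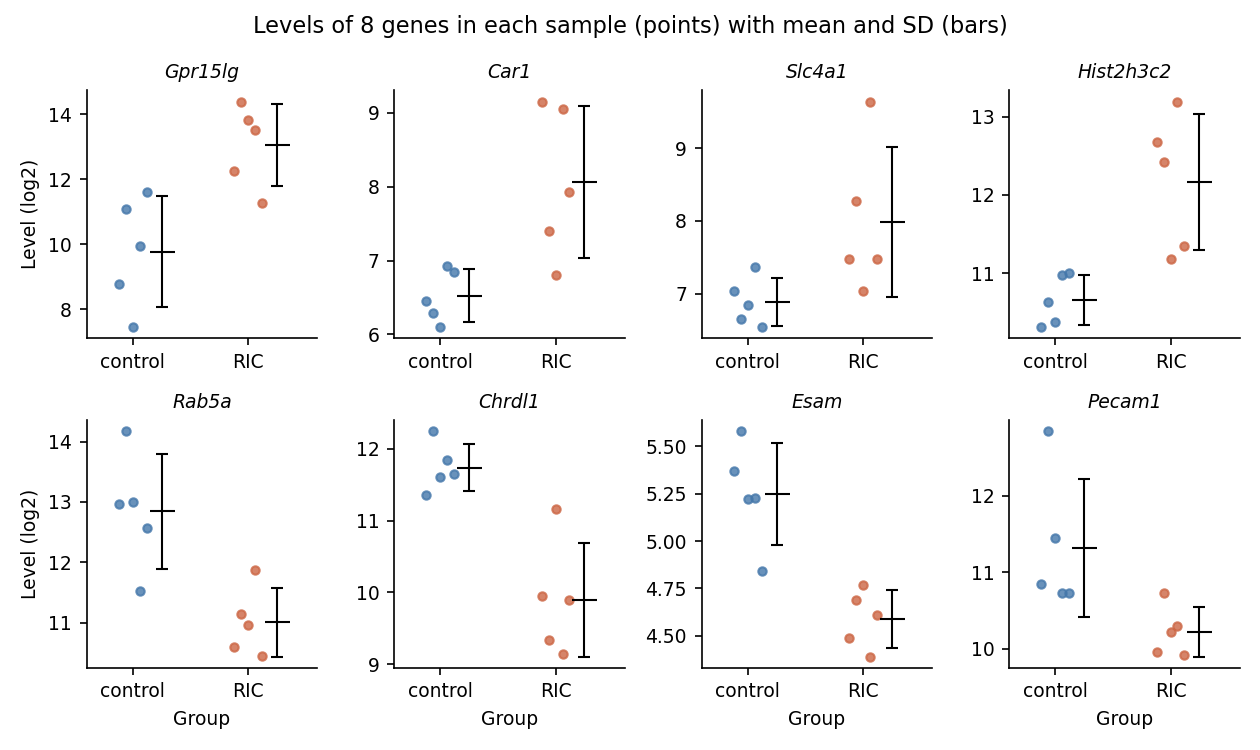
Log2 level (vertical axis) of 8 genes in each control and RIC sample (points, n = 5 per group), with the group mean and SD as black bars. Gpr15lg averaged 9.78 in control and 13.06 in RIC, and Chrdl1 11.74 and 9.90, and none of the 8 passed the adjusted test.

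Abundant RNAs were lower in RIC as a class, and receptor clusters higher, in the values as deposited. Of 5811 clusters with a mean of 6 to 18, 4526 (77.9%) were lower in RIC, with a median difference of -0.22 that turned to 0.03 when quantile normalization was repeated. Of the 1446 receptor clusters, 1105 (76.4%) were higher, with a median difference of 0.09 that was 0.00 by construction after centring on them. The per-sample median of the abundant clusters was 7.65 ± 0.14 in RIC and 7.94 ± 0.23 in control (n = 5 each, exact permutation p = 0.0317). The receptor median was 4.04 ± 0.03 in RIC and 3.96 ± 0.04 in control, with all 5 RIC samples above all controls (exact permutation p = 0.00794). The distance between the medians narrowed by 0.38 in RIC (exact permutation p = 0.0238), and in control sample 2 it was the widest, at 4.44. Without control samples 1 and 2 the difference was -0.25 (exact permutation p = 0.0893). Leaving out RIC sample 3 or RIC sample 5 gave -0.37 and -0.32 (exact permutation p = 0.0556 each), and repeated quantile normalization gave -0.04 (exact permutation p = 0.00794). Removing each array's level-dependent trend gave -0.14 (exact permutation p = 0.0159). In the deposited values the distance was narrowest in RIC sample 5, at 3.37. Control sample 2 lay lowest and RIC sample 5 highest on the first principal component. That component is therefore not taken as separate evidence of a group difference.

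**Figure D2:**
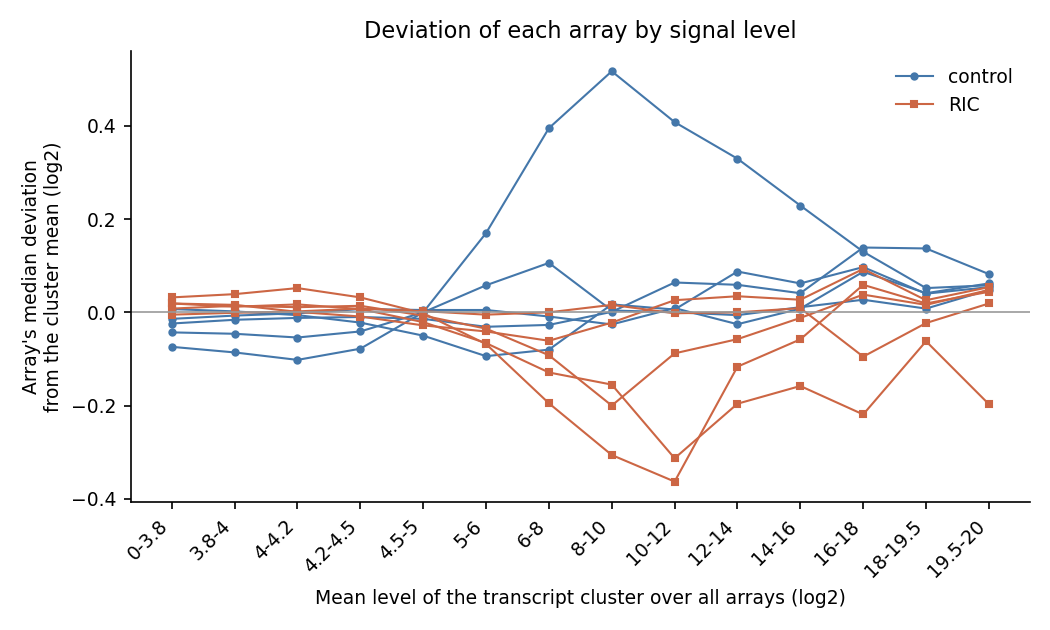
Median deviation of each array from the cluster means (log2, vertical axis) in bins of mean log2 level (horizontal axis), with 1 line per control or RIC sample. Control sample 2 lay 0.52 above the cluster means in the bin from 8 to 10, and RIC sample 5 lay -0.36 from them in the bin from 10 to 12.

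Genes of endothelial cells were lower in RIC, with 12 of 14 measured members lower and a median difference of -0.46. In 95% of random lists of the same levels 6 to 12 were lower, so the count lay within their range. Pecam1, the adhesion molecule of endothelial cells and platelets, measured 10.22 ± 0.33 in RIC and 11.32 ± 0.90 in control, and Esam, an adhesion molecule of the same cell types, 4.59 ± 0.15 against 5.25 ± 0.27. The list passed limma's camera test (Benjamini-Hochberg adjusted p = 0.00138), and its call was lost in a test that allows for the members moving together, with adjusted p = 0.707 with an estimated correlation. By single genes, 0 of 14 passed over all clusters with limma, 2 had an unadjusted p under 0.05, and 1, Esam, passed when adjusted over the list alone. Its median stayed negative under every scaling run, from -0.55 to -0.21, and the list lost its call when arrays were centred on the receptors (adjusted p = 0.0529).

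Platelet genes that could vary were lower in RIC in 22 of 23 cases, with a median difference of -0.26. Random lists of the same levels, which ignore correlation between genes, had 17 of 23 lower (median, 95% range 13 to 21), and 22 lay at the 99.6 percentile of them. A gene at the ceiling varies only if it drops on some array, and the 20 platelet genes never at the ceiling were all 20 lower. Rab27b, a GTPase of granule and exosome release, measured 13.80 ± 0.83 in RIC and 14.98 ± 0.57 in control, and Gng11, a G protein subunit, 5.67 ± 0.26 against 5.93 ± 0.13. The list passed camera (adjusted p = 0.000692), with adjusted p = 0.724 with an estimated correlation. None of the 23 genes passed limma over all clusters or when adjusted over the list alone, and 1 had an unadjusted p under 0.05. The list lost its call without control samples 1 and 2 (adjusted p = 0.098), with the level-dependent trend removed (0.167) and above the receptor 95th percentile (0.12). The median was negative under every scaling run, from -0.34 to -0.04, but camera's direction turned upward after repeated quantile normalization (adjusted p = 0.529).

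Genes of exosome formation and release followed the same direction, with 19 of 22 varying members lower, against 12 to 20 in 95% of random lists of the same levels, and a median difference of -0.13. The tetraspanin Cd81 measured 5.57 ± 0.22 in RIC and 6.04 ± 0.25 in control. Hgs, an ESCRT component, lay on the other side with 4.77 ± 0.06 against 4.60 ± 0.09. The list passed camera (adjusted p = 0.000692), with adjusted p = 0.724 with an estimated correlation, and shared Rab27b with the platelet list. With limma, 0 of 22 genes passed over all clusters or when adjusted over the list alone. An unadjusted p under 0.05 was found for 8, of which 6 were lower and 2 higher in RIC. The call was lost with the level-dependent trend removed (adjusted p = 0.597) and above the receptor 95th percentile (0.107). Camera's direction turned upward after repeated quantile normalization (adjusted p = 0.564), while the median stayed negative under every scaling run.

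Targets of the hypoxia response were lower in 15 and higher in 6 of 22 genes, with a median difference of -0.08. In 95% of random lists of the same levels 8 to 16 were lower, so the count lay within their range. P4ha1, a collagen prolyl hydroxylase, measured 6.41 ± 0.29 in RIC and 7.24 ± 0.58 in control, and the glycolytic enzyme Pgk1 9.84 ± 0.42 against 10.56 ± 0.45. The list passed camera (adjusted p = 0.00951), with adjusted p = 0.564 with an estimated correlation. With limma, 0 of 22 genes passed over all clusters or when adjusted over the list alone, and 2 had an unadjusted p under 0.05. The list lost its call without RIC sample 5 (adjusted p = 0.0604), after repeated quantile normalization (0.21), with the level-dependent trend removed (0.0964), above the median of all clusters (0.172) and above the receptor 95th percentile (0.12). The median stayed negative under every scaling run.

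Liver genes and the olfactory and vomeronasal receptors had positive shifts near background. Liver genes were higher in 16 of 19 cases with a median difference of 0.07, which turned to -0.01 when arrays were centred on the receptors or on the miRNA genes. Albumin (Alb) measured 5.52 ± 0.50 in RIC and 4.94 ± 0.37 in control, and Fetub, a fetuin, 4.06 ± 0.05 against 3.97 ± 0.05. The liver list passed camera (adjusted p = 0.0189), with adjusted p = 0.564 with an estimated correlation. It had adjusted p = 0.11 without control sample 2 and 0.0628 without RIC sample 1. It lost its call under every scaling run, with adjusted p from 0.0616 to 0.369. Of 1276 receptor genes, 975 were higher, with a median difference of 0.09, or 0.00 after centring on them. The receptor list passed camera (adjusted p = 1.55e-06), with adjusted p = 0.515 with an estimated correlation. On rescaled values it passed upward with an estimated correlation too, with adjusted p = 7.29e-05 after centring on the array median and 0.00283 with the level-dependent trend removed. Of the receptors, Or8b47 measured 4.06 ± 0.09 in RIC and 3.62 ± 0.10 in control, and Or5b99 4.16 ± 0.07 against 3.79 ± 0.13. With limma, 0 liver and 0 receptor genes passed over all clusters. An unadjusted p under 0.05 was found for 1 of 19 liver genes and, of 1276 receptor genes, for 140 positive and 6 negative ones. The lists differ in size, and that share was 12% over the receptor clusters and 11.1% over all clusters. Adjusted over the list alone, 0 liver genes and 1 receptor gene passed.

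Erythroid genes were higher in 15 of 23 varying members, with a median difference of 0.10 and adjusted p = 0.221 in camera. The median stayed positive under every scaling run, and the list passed after centring on the array median (adjusted p = 0.00662) and after the level-dependent trend was removed (adjusted p = 0.0002). Both calls were lost, with adjusted p = 0.679 with an estimated correlation after centring and 0.445 with the trend removed, and the deposited values gave 0.805. Without RIC sample 4 the deposited values gave adjusted p = 0.928. Besides Slc4a1, the mitochondrial iron carrier Slc25a37 measured 5.27 ± 0.20 in RIC and 5.02 ± 0.05 in control. Neither passed over all clusters or when adjusted over the list alone.

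Lists of white cells and of acute responses did not pass camera in the deposited values with all samples and no filter on dim clusters. For the monocyte, inflammatory and interferon lists the median was positive (0.01, 0.02 and 0.02) and camera's direction downward, and the medians turned negative when arrays were centred on the receptors. The neutrophil list had adjusted p = 0.195, and passed upward after each centring (0.0306 to 0.0448), above the receptor 95th percentile (0.0289) and without control sample 4 (0.0383). These calls stand against adjusted p = 0.679 with an estimated correlation after centring on the array median and 0.805 in the deposited values. The neutrophil list had a median difference of 0.001 after centring on the array median, and -0.02 after centring on the miRNA genes or the receptors. Its gene for myeloperoxidase (Mpo) measured 4.84 ± 0.23 in RIC and 4.37 ± 0.18 in control. Monocyte genes had adjusted p = 0.771, with the chemokine receptor Ccr2 at 9.46 ± 0.96 against 10.86 ± 1.25. Lymphocyte genes had adjusted p = 0.474, with the B-cell factor Pax5 at 5.64 ± 0.12 against 5.32 ± 0.13. They passed upward above the receptor 95th percentile alone (adjusted p = 0.00893), against adjusted p = 0.805 with an estimated correlation in the deposited values. Among inflammatory genes (adjusted p = 0.646), Il1b, which encodes the cytokine interleukin-1 beta, measured 5.01 ± 0.17 in RIC and 5.68 ± 0.34 in control and was the 1 member to pass when adjusted over the list alone, though its limma adjusted p over all clusters was 0.348. The cytokine gene Tnf measured 4.27 ± 0.10 against 4.07 ± 0.15. The interferon regulator Irf7 measured 7.28 ± 0.41 in RIC and 6.42 ± 0.49 in control, while its list had adjusted p = 0.681. In the immediate early and heat shock list (adjusted p = 0.401), the nuclear receptor Nr4a1 measured 6.37 ± 0.15 against 6.01 ± 0.28.

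The skeletal muscle, heart, brain, ribosomal protein and oxidative phosphorylation lists gave no call at the preset correlation either. That holds for the deposited values with all samples and no filter on dim clusters. Skeletal muscle genes had adjusted p = 0.474, heart genes 0.317 and brain genes 0.539. Heart genes passed downward without control samples 1 and 2 (adjusted p = 0.0312), against adjusted p = 0.805 with an estimated correlation with all samples. Skeletal muscle genes passed downward after each centring and after repeated quantile normalization (adjusted p = 0.0253 to 0.0336), against adjusted p = 0.223 with an estimated correlation after centring on the array median. The oxygen carrier myoglobin (Mb) measured 5.81 ± 0.53 in RIC and 6.46 ± 0.63 in control, and cardiac actin (Actc1) 5.00 ± 0.09 against 5.22 ± 0.19. Ribosomal protein genes split into 129 higher and 155 lower (adjusted p = 0.383), and oxidative phosphorylation genes into 56 higher and 59 lower (adjusted p = 0.474). The direction of the last 2 lists depended on the scaling and on the filter. Above the receptor 95th percentile both passed upward, with adjusted p = 0.00711 for ribosomal protein genes, against 0.873 with an estimated correlation and no filter. After the level-dependent trend was removed, both passed upward, with adjusted p = 2.49e-06 for ribosomal protein genes and 0.00819 for oxidative phosphorylation genes. Both calls were lost, with adjusted p = 0.445 with an estimated correlation on the same values. Without control sample 1 the ribosomal list passed downward (adjusted p = 0.00598), against adjusted p = 0.873 with an estimated correlation with all samples.

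Among miRNA genes, 4 of 398 clusters rose in RIC when adjusted among themselves, and 0 fell. Mir344b-1 rose from 3.88 ± 0.13 to 4.30 ± 0.08 (n = 5 each, log2 difference 0.42, SE 0.07, limma adjusted p = 0.0282), and Mir32 from 4.19 ± 0.09 to 4.59 ± 0.14 (adjusted p = 0.0356). Mir350, represented by a pair of clusters with identical values, rose from 3.59 ± 0.10 to 3.93 ± 0.08 (adjusted p = 0.0282), and is named because so few passed, after its values were seen. For each of these genes all 5 RIC samples lay above all 5 controls, as they did for 875 clusters in all. The receptor gene Or8b47 was among those clusters. Groups without overlap in either direction made up 1.74% of clusters, against 0.79% by chance. The levels of Mir344b-1, Mir32 and Mir350 were dim, with only the RIC mean of Mir32 above the receptor 95th percentile. None of the 4 clusters was called without control sample 1, 2 or 4 or without RIC sample 1, 2 or 5, and without control sample 4 the call was Mir296 instead (adjusted p = 0.0486). Without control sample 5 Mir344b-1 alone was called, and without RIC sample 3 Mir344b-1 and Mir32. Without control sample 3 or RIC sample 4, 3 of the 4 were called, Mir32 being lost. Adjusted over all transcript clusters 0 of the 4 passed, and 0 miRNA genes were called after centring each array or removing the level-dependent trend, with 36 to 42 at an unadjusted p under 0.05.

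Other miRNA genes that the naming rule picked did not pass with all samples. Without RIC sample 4 Mirlet7f2 was called (log2 difference 0.914, limma adjusted p = 0.0383). Mirlet7f2 measured 5.05 ± 0.43 in RIC and 4.30 ± 0.20 in control, Mir30c2 4.71 ± 0.52 against 4.14 ± 0.24, Mir483 5.57 ± 0.28 against 5.03 ± 0.31, and Mir296 4.84 ± 0.14 against 4.43 ± 0.17. In the other direction, Mir6216 measured 4.23 ± 0.43 against 4.87 ± 0.42, the myeloid and platelet miRNA gene Mir223 4.47 ± 0.57 against 5.09 ± 0.33, and Mir3074 4.06 ± 0.11 against 4.31 ± 0.10, and Mir346 differed by -0.36 from 4.36 ± 0.28 in control. Of the 42 miRNA gene clusters (10.6%) at an unadjusted p under 0.05, 35 had a positive and 7 a negative difference. That share was 11.1% over all clusters. Over the receptor clusters it was 12%, with 166 positive and 7 negative, so neither the share nor its direction set the miRNA genes apart.

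**Figure D3:**
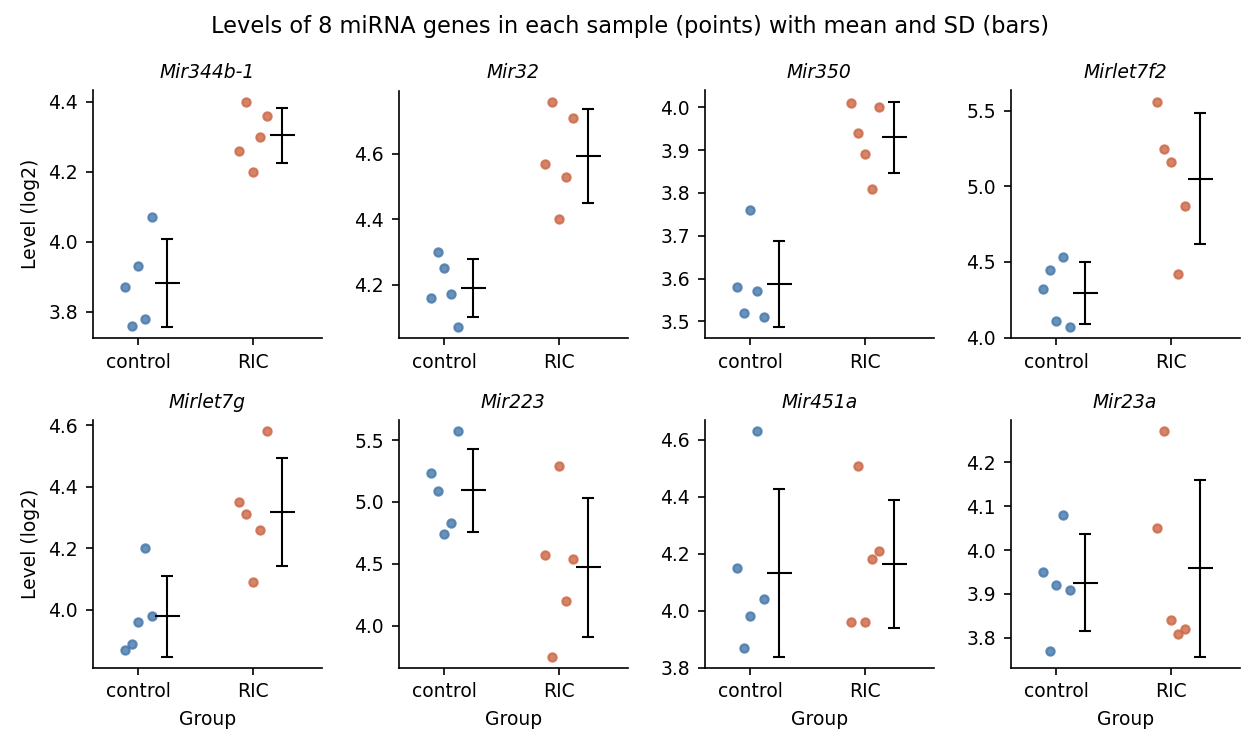
Log2 level (vertical axis) of 8 miRNA genes in each control and RIC sample (points, n = 5 per group), with the group mean and SD as black bars. Mir344b-1, Mir32 and Mir350 separated the groups completely, while Mir451a averaged 4.13 in control and 4.16 in RIC.

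The let-7 family, miRNAs that restrain growth and developmental genes, was higher in RIC at 9 of 10 measured genes, with a median difference of 0.33. Mirlet7g measured 4.32 ± 0.18 in RIC and 3.98 ± 0.13 in control, and with Mirlet7f2 it passed when adjusted over the list alone, while 0 of the 10 passed among the 398 and 3 had an unadjusted p under 0.05. In camera the family did not pass (adjusted p = 0.0818, and adjusted p = 0.398 with an estimated correlation). It passed in fry (adjusted p = 0.0278), which asks whether its genes moved one way on balance, and in camera after the level-dependent trend was removed (adjusted p = 0.0167), against adjusted p = 0.134 with an estimated correlation on the same values. Its median stayed positive under every scaling run, from 0.24 to 0.33.

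With camera, 0 of the 13 miRNA lists passed, and 1, the let-7 family, had an unadjusted p under 0.05. Platelet miRNA genes were lower in 6 of 9 cases (median difference -0.06, adjusted p = 0.533), and leukocyte miRNA genes had a median difference of 0.04 against a downward camera direction (adjusted p = 0.606). The remaining 10 lists had adjusted p = 0.871 each. Their median differences were 0.07 for erythrocyte and haemolysis, 0.01 for muscle, 0.07 for endothelial and angiogenic, 0.07 for hypoxia, 0.07 for conditioning miRNAs from the literature, 0.05 for liver, 0.03 for brain, 0.07 for the miR-17-92 cluster and paralogues, 0.10 for the miR-29 and miR-30 families and 0.10 for the Dlk1-Dio3 cluster. Of these medians, 8 turned negative when arrays were centred on the receptors, and camera's direction was downward for the conditioning, brain and miR-17-92 lists. By single genes, 0 members of the 13 lists passed among the 398. Adjusted over the list alone, 1 passed besides the let-7 genes, Mir296 in the endothelial and angiogenic list.

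miRNA genes linked to ischemia, muscle and blood cells had small differences. Mir144, co-transcribed with Mir451a in red-cell precursors, differed by 0.16, the hypoxia-induced Mir210 by -0.30, the muscle gene Mir133a1 by 0.29, and the liver gene Mir122 by 0.25. Differences for Mir451a (0.03), Mir16 (-0.04), Mir23a (0.03), Mir24-2 (0.07), Mir126a (-0.03) and Mir1 (0.01) did not pass, and all but those of Mir16 and Mir126a changed sign under some scalings. The distance of Mir451a from Mir23a, built after the plasma haemolysis index of the mature miRNAs, was 0.21 ± 0.20 in RIC and 0.21 ± 0.20 in control (difference -0.002, exact permutation p = 1). Both genes lay under the receptor 95th percentile on average, and haemolysis of the mature miRNAs was not measured. The per-sample median of the 158 miRNA gene clusters above background was 4.58 ± 0.07 in RIC, a difference of 0.086 from control (n = 5 each, exact permutation p = 0.119). That difference fell to 0.022 after centring on the array median and to 0.001 after centring on the receptors.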

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

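No test beyond the gap between samples was run on these values, and the genes among them were named by the rule given with the processing. Of 188 groups of samples, 14 (7.4%) had a highest or lowest sample separated from the rest by a large share of the group's range, and chance gives about 1 in 20. Control sample 2 accounted for 5 of the 14. It was highest for Zwint (13.9, others 11.18 to 11.76), Gng11 (6.16, others 5.84 to 5.91), Pgk1 (11.36, others 10.31 to 10.4) and Nr4a1 (6.49, others 5.83 to 5.97), and lowest for Mir363 (4.4, others 5.01 to 5.19).

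Control sample 4 was highest for Mir296 (4.72, others 4.32 to 4.39) and for the distance of Mir451a from Mir23a (0.55, others 0.06 to 0.2). Control sample 3 was highest for Mir350, at 3.76 against 3.51 to 3.58. Control sample 1 was highest for the unnamed cluster TC0900002592.rn.1 (11.74, others 8.99 to 9.7) and had the most clusters at the ceiling (1366, others 1343 to 1349).

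Among RIC samples, sample 4 was highest for Slc25a37 (5.62, others 5.13 to 5.21) and Mir1 (4.21, others 3.92 to 4), and lowest for Mb (4.9, others 5.91 to 6.3). RIC sample 5 was lowest for Mir150, at 3.52 against 3.59 to 3.61.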

How the results depend on the processing

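Chosen only after the data were seen were the removal of the level-dependent trend, centring on the receptors, the receptor 95th percentile as a filter, leaving out constant clusters, counting identical clusters once, adjusting over all clusters, leaving out control samples 1 and 2 together, the estimated correlation on rescaled values, and the gene lists and the spread as results. The cause was not tested for any change below unless given. No setting gave a transcript cluster past the adjusted threshold, while an unadjusted p under 0.05 gave 795 clusters with a fold of at least 1.5 and 265 with a fold of at least 2. The count of 4 called miRNA gene clusters became 0 with each centring and with the trend removed. It was also 0 with only clusters above the median of all and with p adjusted over all clusters. An unadjusted p under 0.05 gave 3, 1 up and 2 down, with a fold of at least 1.5, and 0 with a fold of at least 2. The adjusted count became 1 after repeated quantile normalization and above the receptor 95th percentile, and 2 among the 199 with the higher mean. Without control samples 1 and 2 it was 0, where fewer samples remained. Leaving out each sample gave counts of 0 to 4, and between 0 and 3 of the original 4 were among them.

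For miRNA lists, 1 instead of 0 passed with each centring, with the trend removed and with fry, and leaving out each sample gave 0 to 1. With an estimated correlation 0 passed after centring on the array median (let-7 adjusted p = 0.15) or with the trend removed (0.134). The 6 gene lists became 0 with an estimated correlation, 0 with fry, and 1, the receptors, with an estimated correlation after centring on the array median or with the trend removed. Camera's direction reversed after repeated quantile normalization for platelet (adjusted p = 0.529), exosome biogenesis (0.564), ribosomal (1.06e-15) and oxidative phosphorylation genes (0.000909), with the trend removed for the last 2 (2.49e-06 and 0.00819), and above the receptor 95th percentile for the same 2 (0.00711 and 0.0202). The distance of Mir451a from Mir23a was -0.048 to 0.083 when each sample was left out. The narrowing of the abundant-to-receptor distance was -0.254 without control samples 1 and 2 and -0.436 to -0.263 when each sample was left out. The median of detected miRNA genes kept its side of the threshold in all settings able to cross it.

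Samples that share a replicate number are separate animals, and their deviations correlated at -0.10 to 0.17. Samples with different numbers were not compared in this way, so these values do not settle whether the numbers pair them. With the replicate block, 0 miRNA gene clusters and 1 miRNA list passed, and the abundant-to-receptor difference of -0.377 had an exact p of 0.125, which decides nothing, since sign flips of 5 pairs cannot give less than 0.0625. Of 2021 comparisons over 88 named clusters, 1922 kept direction and side, 59 lost and 2 gained a call, and 38 changed sign without a call. Of 321 over 14 lists that passed in any setting, 231 kept both, 40 lost and 26 gained a call, 16 changed direction without one and 8 reversed. Averaging orthologue probe sets was not run. Signal near background limits the miRNA genes, and the ceiling limits platelet and globin genes.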

Other observations

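The tests of the level-dependent shift, of platelet, erythroid, endothelial and histone genes, and of let-7 genes against clusters of the same level, the receptor sets with identical clusters counted once, the counts of lower genes against random lists or never at the ceiling, and the level-matched values with samples left out were chosen only after the result was seen. Replication-dependent histone genes, which package newly made DNA and whose transcripts mostly lack poly(A) tails, were higher in RIC at 23 of 27 measured genes, with 7 at an unadjusted p under 0.05, all 7 positive. Their median difference was 0.14, against a median of -0.07 for 10000 random lists of the same levels. Each sample's median over its level-matched clusters was 0.19 ± 0.25 in RIC and -0.22 ± 0.12 in control (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0397 over 5 lists). Among the examples, H2ac4 differed by 0.90 and Hist1h2ail1 by 0.62, while Hist1h4b differed by -0.42. A shift of these genes beyond others of their level may be a feature of the RIC samples, as a hypothesis found on the same data.

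Erythroid genes had a level-matched median of 0.13 ± 0.23 in RIC and -0.16 ± 0.18 in control (exact permutation p = 0.0238, adjusted p = 0.0397). The difference of 0.28 rested on single samples, with 0.18 without RIC sample 4 (exact permutation p = 0.0635) and 0.21 without control sample 2 (exact permutation p = 0.0794). More erythroid RNA in the RIC samples is a candidate explanation that these samples leave open, and red cells broken during sampling were not tested apart from it, since the main globin genes were at the ceiling. The erythroid and histone values were both highest in RIC sample 4, at 0.54 and 0.57. For endothelial genes the level-matched medians were -0.07 ± 0.16 in RIC and 0.09 ± 0.18 in control, with an exact permutation p of 0.167. Their median of -0.46 lay at percentile 0 of random lists of the same levels (-0.20 to 0.02), which ignore correlation between genes, so whether they were lower than others of their level stays open.

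The fall of abundant clusters with the rise of receptor clusters was weighed between a distortion of the array values and less platelet RNA. The 76.4% of receptor clusters higher in RIC are part of the pattern itself, so they do not test a distortion that depends on signal level, which stays open. For less platelet RNA the evidence was mixed, since the platelet median of -0.26 lay at the 0.5 percentile of random lists of the same levels, which ignore correlation between genes, while the level-matched medians of the samples had an exact permutation p of 0.54. The count of 7665 clusters at an unadjusted p under 0.05 was matched by 1 of 100 splits of the samples, the real one. The highest other split gave 6663. So high a count was rare among splits, which excludes neither chance nor a technical difference between the groups. A difference made by RIC stays open as untested.

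The 4 miRNA gene clusters were weighed against the rise of dim clusters shared with unexpressed genes. Of random receptor sets of the same size and levels, 1.15% gave 4 or more calls, and 2.27% of sets drawn without replacement. The gene Mir350 enters as a pair of identical clusters, and with such clusters counted once, 2.24% and 3.73% of sets gave 3 or more calls. The miRNA genes thus gave more calls than most receptor sets. Such sets come from the same samples and ignore correlation between clusters, so they do not exclude that rise as the cause. Only 1 of 100 splits, the real one, gave as many as 4, and the highest other gave 1. So high a count was rare among splits of the deposited values, which does not exclude chance. The rise of the 4 clusters may still depend on the scaling, since 0 were called when each array was centred on the receptors, where the log2 differences became 0.34 for Mir344b-1, 0.32 for Mir32 and 0.26 for Mir350.

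The let-7 genes were weighed against the same rise of dim clusters and against signal shared between near-identical copies. Their level-matched medians were 0.10 ± 0.07 in RIC and -0.14 ± 0.09 in control (exact permutation p = 0.0159, adjusted p = 0.0397). They thus rose more than clusters of the same level. Their median of 0.33 lay at percentile 100 of random lists of the same levels (-0.08 to 0.07), which ignore correlation between genes. For these 10 genes, the values argue against a rise shared by clusters of their level as the sole cause. The adjustment covered only lists chosen after their results were seen and does not allow for that choice, so chance stays open. The mean residual correlation among let-7 clusters lay at the 61.4 percentile of random lists of the same levels, which left shared signal open. A higher level of let-7 primary transcripts in RIC samples may be followed up as a hypothesis, with mature let-7 not analysed here.

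For the counts of 0 transcript clusters and 0 miRNA lists, other splits decide nothing, because all 100 must give at least 0, and the highest other split gave 1 for each. For the gene lists chance was not excluded either, and their count was common among splits. The 6 lists were reached or exceeded by 41 of 100 splits, the real one included, and the highest other split gave 13.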
